A study of Drosophila melanogaster with 12 samples.

How the data were processed

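Total RNA from sorted mesodermal cells of Drosophila melanogaster embryos at late stage 11 to early stage 12 was measured on 12 single-colour oligonucleotide arrays. Cells were sorted for GFP driven in Twist-expressing cells, and about 2 to 5 micrograms of RNA went into each biotin labelling. The labels give 4 groups of 3 arrays: wild type set 1, Slou gain of function, wild type set 2 and Msh gain of function. Nothing in the labels says whether the 3 arrays of a group came from separate embryo collections, so the p-values measure only the spread between arrays, which may be technical.

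The deposited table holds one value per probe set and array, on a log2 scale. Per the labels the authors used the R package affy, whose version was not given; the background correction, scaling and summary method were not stated. The base of the logarithm was read from the size of the values. The deposited log2 values fell into 2 separately scaled parts. Arrays of wild type set 1 and Slou had medians of 2.59 to 2.72 and 75th percentiles of 5.65 to 5.68. Arrays of wild type set 2 and Msh had medians of 3.85 to 3.91 and 75th percentiles of 7.56 to 7.58. Correlations between arrays were 0.889 to 0.903 within the former part, 0.925 to 0.944 within the latter, and 0.884 to 0.900 across them.

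Of 18952 probe sets, 183 controls were left out and 18769 were tested. Of these, 13647 were annotated with 1 gene, 402 with several genes and 4720 with none; genes are named only for the first kind. The annotation of 13544 probe sets matched the naming table of the fly reference, and 11982 distinct genes were named. No genome coordinates are given, since the array annotation used here names no build. Number of arrays and distance from background limit the precision. The median SD between the 3 arrays of wild type set 1 was 1.22 for probe sets below a log2 value of 2 and 0.0479 above 8.

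Probe sets were tested with limma 3.58.1 in R 4.3.3, with moderated statistics and Benjamini-Hochberg adjustment at 0.05. Slou was compared with wild type set 1, and Msh with wild type set 2, each in a fit of the 6 arrays that share a scaling. The difference between the Slou effect and the Msh effect, and the difference between the wild-type sets, came from a fit of all 12 arrays with 4 group means. Standard errors of fold changes are the moderated ones from limma.

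These tests depart from those fixed before the data were examined, which required each call to hold against both wild-type sets in a fit of 12 arrays, because the labels do not say which wild-type set was made with which gain-of-function arrays. Comparing within a scaling was decided once the scale difference was seen and before any fit. Fitting 6 arrays rather than 12 was decided after the numbers of calls had been seen. The planned test called 572 probe sets for Slou and 421 for Msh. Within a scaling, the fit of 12 arrays called 1591 and 1741, the fit of 6 arrays 434 and 1278, and the fit of 6 arrays with an intensity trend 2380 and 3621.

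Gene lists were tested with camera from limma over 1 probe set per gene, the one with the highest mean, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 26 lists. All 26 lists were written before the data were examined and asked for 395 entries, of which 310 were measured; the other entries had no probe set named for them in the annotation used here. The Wingless list was measured for 4 of 15 genes, fusion machinery for 5 of 11 and Hox genes for 4 of 10. Each was also tested with an estimated correlation. The estimate exceeded the preset value for some lists, at 0.172 for fusion-competent myoblasts in Slou, but not for others. For contractile genes it was -0.00791 in Slou and -0.00499 in Msh. Their unadjusted camera p in Slou still went from 1.29e-06 to 0.00644, so a larger correlation cannot be the reason there. A member counts as having risen or fallen where its probe set passed among all probe sets tested; counts adjusted over the list alone are given beside these.

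The genes named were fixed by a rule written before the data were examined. It took slou and Dr, the 12 called genes with the largest change in each direction for Slou and for Msh, 8 in each direction for Slou against Msh, and up to 4 members with the smallest p of each list described. The rule ranked by the smaller fold against the 2 wild-type sets; ranking here used the fold within a scaling. Other list members and genes called in both comparisons were singled out after their values were seen.

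The tests were checked on simulated data, in which changes were added to real spreads. For Slou, 0 of 50 changes of 0.5 on the log2 scale, 7 of 50 of 1, 16 of 50 of 2 and 25 of 50 of 4 were recovered, with 5 false calls. For Msh the numbers were 0, 12, 27 and 33 of 50, with 7 false calls. All 3 simulated lists of 17 members shifted by 0.5 were recovered, with 0 false lists. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes pass falsely.

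Alternatives were quantile normalization over 12 arrays, centring on the array median, leaving out probe sets under the 40th percentile of the mean, the replicate letter as a block, an intensity trend, a minimum fold of 1.5, other wild-type controls, other contrasts, and leaving out each array. The 3 main tests within a scaling, and both wild-type sets after quantile normalization, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.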

Results

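The arrays compared sorted mesodermal cells that overexpressed 1 of 2 homeodomain transcription factors with wild-type mesodermal cells. Slou (slouch, also S59) and Msh (muscle segment homeobox, gene symbol Dr) each mark subsets of muscle founder cells. There were 3 arrays for each gain of function and 3 in each of 2 wild-type sets. Of the 18769 probe sets, 8.76% to 20.6% lay below a log2 value of 0 on an array.

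Expression of slou itself identified the Slou arrays. The slou probe set averaged 5.58 ± 0.12 (SD, n = 3) in wild type set 1 and 11.07 ± 0.05 (SD, n = 3) in Slou, a rise of 5.48 on the log2 scale (SE 0.11, limma adjusted p = 0.00152). In the Msh arrays slou fell by 0.57 (SE 0.10, adjusted p = 0.0458). The probe set of Dr did not pass in Msh, with a change of 0.32 (SE 0.14, adjusted p = 0.254), from 9.03 ± 0.23 to 9.36 ± 0.02 (SD, n = 3 each). No rise of Dr was thus detected in the arrays labelled Msh, whose overexpression rests on the labels alone; whether this probe set can detect the transgene, or the labels or values of these arrays are in doubt, was left open. Dr fell by 2.80 in Slou (SE 0.14, adjusted p = 0.00569).

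**Figure D1:**
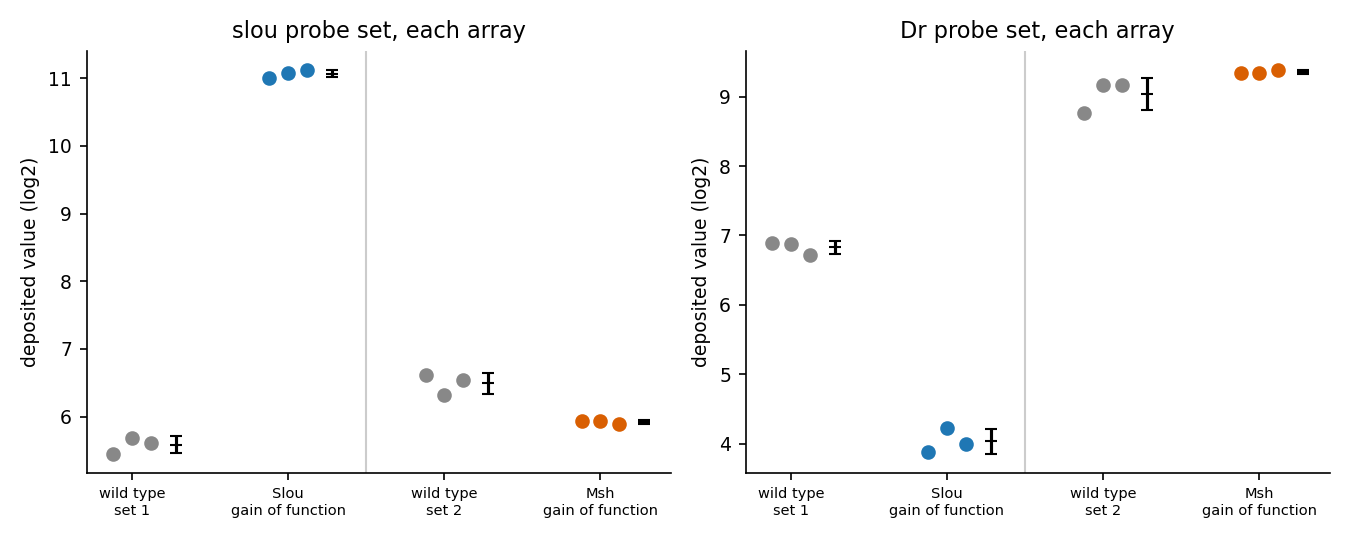
Deposited log2 values of the slou and Dr probe sets on each of the 12 arrays, with the mean and SD of each group of 3 beside the points; the vertical line parts the 2 separately scaled parts. The slou values of the 3 Slou arrays average 11.07, above wild type set 1 at 5.58, while Dr differs between wild type set 2 and Msh by 0.32.

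Slou was compared with wild type to ask which mesodermal genes change when this factor is present throughout the mesoderm. Several other factors that specify individual muscles fell. The Iroquois homeobox genes caup and ara fell by 2.28 (SE 0.15) and 1.45 (SE 0.13), and mirr fell too (adjusted p = 0.0153). nau, the fly MyoD relative, fell by 1.63 (SE 0.14), Ptx1 by 2.26 (SE 0.26) and tey by 3.22 (SE 0.29), while ap, a LIM homeobox gene, rose by 1.46 (SE 0.14). Collagen IV chains fell, as did the lipid carrier apolpp, whereas muscle myosin light chains rose.

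Among 19 measured muscle identity factors 2 rose, 7 fell and 10 did not pass. Adjusted over the list alone, 2 rose and 9 fell. The list holds slou and Dr themselves: the 2 that rose were ap and the overexpressed slou, and Dr was among the 7 that fell. It was not tested without them. The list's median was -0.72 (adjusted p = 0.000867; adjusted p = 0.107 with an estimated correlation). Of 6 genes of fusion-competent myoblasts, the cells that fuse with founders, 2 rose, and 4 rose when adjusted over the list alone (median 0.56, adjusted p = 6.37e-05; adjusted p = 0.107 with an estimated correlation). These were sns, a cell adhesion receptor of fusion, by 1.59 (SE 0.18) and blow by 0.70 (SE 0.09). Vrp1 had a change of 0.68 (SE 0.10) that did not pass.

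Genes of contractile proteins were higher in Slou. Of 17 measured, 5 rose and none fell, and adjusted over the list alone 8 rose and 1 fell (median 0.45, adjusted p = 1.67e-05; adjusted p = 0.107 with an estimated correlation). Mlc2 and Mlc1, myosin light chains, rose by 1.33 (SE 0.12) and 1.01 (SE 0.11), up, a troponin T, by 1.28 (SE 0.14), TpnC73F, a troponin C, by 1.21 (SE 0.10), and bt, a titin-like kinase, by 0.98 (SE 0.14). Of 11 stress genes 3 rose, and adjusted over the list alone 4 rose and 1 fell (median 0.81, adjusted p = 0.00282; adjusted p = 0.107 with an estimated correlation). They were puc, a JNK pathway phosphatase, by 1.18 (SE 0.15), kay, the fly Fos, by 0.92 (SE 0.09), and Hsp27, a small heat shock protein, by 0.86 (SE 0.12). The 11 glycolysis genes had a median of 0.42 (adjusted p = 0.0490; adjusted p = 0.288 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone.

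The cardiac, fat body and hemocyte lists had lower medians in Slou, while those of visceral mesoderm and adult muscle precursors did not pass (adjusted p = 0.135 and 0.0726). Of 11 cardiac genes 4 fell, and adjusted over the list alone 1 rose and 5 fell (median -0.95, adjusted p = 0.00830; adjusted p = 0.111 with an estimated correlation). Hand, a heart bHLH factor, fell by 2.21 (SE 0.23), the T-box genes Doc2 and Doc1 by 1.49 (SE 0.13) and 1.09 (SE 0.12), and svp, a nuclear receptor, by 0.98 (SE 0.13). Of 4 fat body genes 2 fell, and 3 fell adjusted over the list alone (median -0.71, adjusted p = 0.00276; adjusted p = 0.107 with an estimated correlation). They were apolpp, by 2.77 (SE 0.14), and svp, which the cardiac list also holds. Of 17 hemocyte genes 2 rose and 4 fell, and adjusted over the list alone 3 rose and 6 fell (median -0.45, adjusted p = 0.0182; adjusted p = 0.238 with an estimated correlation). The collagen IV genes vkg and Col4a1 fell by 2.97 (SE 0.13) and 2.62 (SE 0.09), and gcm, a glial and blood cell factor, by 1.75 (SE 0.11). SPARC, a collagen-binding matrix protein, rose by 1.12 (SE 0.09).

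The neural and cell cycle lists also had lower medians in Slou. Of 17 neural genes 2 fell, and 6 fell adjusted over the list alone (median -0.58, adjusted p = 1.67e-05; adjusted p = 0.107 with an estimated correlation). nerfin-1 fell by 1.15 (SE 0.11) and pros by 0.98 (SE 0.10); both are neuronal differentiation factors. All 17 cell cycle genes had a negative change, with 0 passing over all genes or adjusted over the list alone (median -0.19, adjusted p = 0.000337; adjusted p = 0.107 with an estimated correlation). In the Slou arrays the added poly-A control transcripts averaged 6.04 ± 0.11 (SD, n = 3), against 6.71 ± 0.03 (SD, n = 3) in wild type set 1.

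In all, 434 probe sets passed, 232 higher and 202 lower, for 182 and 159 named genes. On each of the 434, the 3 Slou values lay wholly above or below the 3 wild-type values, as did 25.3% of all probe sets, where chance gives 10%. The largest rises were those of CG13794 at 6.99 (SE 0.37), Nach, a sodium channel gene, at 5.76 (SE 0.57), and slou. CG31601, CG32572, CG10621, Arr1, be, CG14947, CG34353, CG32485 and beat-Ic followed, down to 3.15. The largest falls were those of CG12594 at -4.50 (SE 0.27), Obp99c, an odorant-binding protein gene, at -4.45 (SE 0.27) and CG14857 at -4.17 (SE 0.24). CG5973, unpg, CG15209, CG31463, CG10026, CG1958, CG9664, CG14856 and CG43336 followed, to -3.23. In 9 of the 12 higher and 8 of the 12 lower genes, 1 group averaged below a log2 value of 2, near background, so their sizes and order are uncertain.

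The count fell to 0 without replicate C of wild type set 1 (2436 at an unadjusted p under 0.05 by limma) and to at most 49 without any other array. With the replicate letter as a block it was 0. Deviations from the group means correlated by only -0.0143 to 0.0304 between arrays of the same letter over both comparisons. The letters thus showed no pairing for a block to remove, while the block left fewer degrees of freedom. Against wild type set 2 after quantile normalization Mlc2, Mlc1, TpnC73F, bt, sns and Hsp27 had a negative change in Slou, -0.93 for Mlc2. Those rises were thus seen only against wild type set 1. The comparison with set 2 crosses the 2 scaled parts, and an offset between them could also turn a sign. It therefore cannot decide which direction is right. Further genes may turn too, since only the fold nearer 0 of the 2 sets was kept. Against set 2 as deposited the contractile and fusion-competent myoblast lists turned down (adjusted p = 0.0248 and 0.0361), and with both sets as planned 2 of the 10 lists passed.

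Msh was compared with wild type with the same question. Against wild type set 2, genes of contractile proteins were lower: Tm2, a tropomyosin, fell by 1.91 (SE 0.13), Msp300, a nesprin of muscle nuclei, by 1.81 (SE 0.12), Mlc1 by 1.61 (SE 0.12) and Mlc2 by 1.46 (SE 0.09). Against wild type set 1 as deposited the direction of the contractile list reversed, as given below. Glycolytic enzymes were also lower, Eno by 1.38 (SE 0.08) and Tpi by 1.18 (SE 0.13), while 8 of 17 cell cycle genes rose. As lists, the contractile, glycolysis and cell cycle genes each had an adjusted p = 0.0812 with an estimated correlation. Of the muscle identity factors, kn fell by 0.84 (SE 0.08), Six4 by 0.68 (SE 0.07) and eve by 0.67 (SE 0.09), and ap rose by 1.13 (SE 0.10).

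Of 17 contractile genes 1 rose and 8 fell, and adjusted over the list alone 2 rose and 13 fell (median -0.83, adjusted p = 2.66e-05; adjusted p = 0.0812 with an estimated correlation). The riser was Zasp52, a Z-disc protein, by 0.86 (SE 0.10). Of 11 glycolysis genes 6 fell, and 8 fell adjusted over the list alone (median -0.61, adjusted p = 6.75e-05; adjusted p = 0.0812 with an estimated correlation). Pfk fell by 0.72 (SE 0.11) and Hex-A by 0.61 (SE 0.07). Of 17 cell cycle genes 8 rose, and 13 rose adjusted over the list alone (median 0.44, adjusted p = 1.61e-07; adjusted p = 0.0812 with an estimated correlation). Incenp, a chromosomal passenger protein, rose by 0.63 (SE 0.07), Mcm6 and Mcm2, replication helicase subunits, by 0.61 (SE 0.07) and 0.52 (SE 0.07), and CycB3 by 0.55 (SE 0.07). In the Msh arrays, the 3' minus 5' difference of the Act5C control probe sets was 2.23 ± 0.10 (SD, n = 3), against 1.44 ± 0.04 (SD, n = 3) in wild type set 2.

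The founder cell, receptor tyrosine kinase, Wingless, Dpp and stress lists had higher medians in Msh, while the Notch list did not pass (adjusted p = 0.141). Of 10 founder cell genes 4 rose, and adjusted over the list alone 7 rose and 1 fell (median 0.35, adjusted p = 0.00205; adjusted p = 0.162 with an estimated correlation). rols, a fusion adaptor of founder cells, rose by 0.74 (SE 0.07) and pyd by 0.58 (SE 0.07). Of 13 receptor tyrosine kinase pathway genes 3 rose, and 6 rose adjusted over the list alone (median 0.32, adjusted p = 0.000241; adjusted p = 0.142 with an estimated correlation). pyr, an FGF ligand, rose by 0.85 (SE 0.12) and aos, an EGF receptor antagonist, by 0.72 (SE 0.08). Of 15 Wingless pathway genes asked for, 4 were measured, without wg or arm, and of these 2 rose, and 3 rose adjusted over the list alone (median 0.44, adjusted p = 0.00511; adjusted p = 0.162 with an estimated correlation), nkd by 0.60 (SE 0.08) and slp2 by 0.48 (SE 0.09). Of 10 Dpp pathway genes 2 rose, also adjusted over the list alone (median 0.22, adjusted p = 0.0268; adjusted p = 0.162 with an estimated correlation), the ligand dpp by 0.94 (SE 0.10) and Dad by 0.57 (SE 0.07). Of 11 stress genes 2 rose, and adjusted over the list alone 5 rose and 1 fell (median 0.39, adjusted p = 0.0120; adjusted p = 0.162 with an estimated correlation), Hsp68 by 0.69 (SE 0.10) and DnaJ-1 by 0.46 (SE 0.07).

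The epidermal, tracheal, gland and gut, and neural lists had higher medians in Msh, and the hemocyte and fat body lists lower ones. The germline list did not pass (camera adjusted p = 0.106). Of 10 epidermal genes 3 rose, and 5 rose adjusted over the list alone (median 0.33, adjusted p = 0.000646; adjusted p = 0.142 with an estimated correlation). These were sdt and crb, apical polarity genes, by 0.77 (SE 0.11) and 0.57 (SE 0.07), and grh by 0.68 (SE 0.10). Of 10 tracheal, gland and gut genes 4 rose, and 7 rose adjusted over the list alone (median 0.44, adjusted p = 0.00125; adjusted p = 0.162 with an estimated correlation), among them btl, the tracheal FGF receptor, by 1.10 (SE 0.13) and sage by 1.03 (SE 0.19). Of 17 neural genes 4 rose and 1 fell, and adjusted over the list alone 6 rose and 2 fell (median 0.22, adjusted p = 0.0160; adjusted p = 0.384 with an estimated correlation). sens, a sensory organ factor, rose by 1.22 (SE 0.07) and fne fell by 0.85 (SE 0.09). Of 17 hemocyte genes 6 fell, also adjusted over the list alone (median -0.20, adjusted p = 0.0182; adjusted p = 0.162 with an estimated correlation). Col4a1 fell by 2.57 (SE 0.09), vkg by 2.53 (SE 0.10), PPO1, a prophenoloxidase, by 0.97 (SE 0.07) and Glt by 0.91 (SE 0.09). Of 4 fat body genes apolpp alone fell, by 1.33 (SE 0.08), also adjusted over the list alone (median -0.78, adjusted p = 0.0268; adjusted p = 0.162 with an estimated correlation). The poly-A control transcripts averaged 9.11 ± 0.15 (SD, n = 3) in Msh and 10.75 ± 0.45 (SD, n = 3) in wild type set 2.

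Muscle identity factors as a list did not pass in Msh. Of 19 measured, 1 rose and 6 fell, and adjusted over the list alone 5 rose and 6 fell. The list holds both overexpressed factors: slou was among the 6 that fell over all probe sets, and Dr did not pass there. Their median was 0.29 and their mean 0.24, whereas the test's direction was down (adjusted p = 0.770).

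In all, 1278 probe sets passed in Msh, 536 higher and 742 lower, for 406 and 623 named genes. On each of the 1278 the 3 Msh values lay wholly above or below the 3 wild-type values, as did 32.8% of all probe sets, where chance gives 10%. The largest rises were those of CG15125 at 5.26 (SE 0.33), MtnD, a metallothionein, at 5.16 (SE 0.68) and CG13794 at 5.15 (SE 0.13). wat, Ugt37B1, zormin, CG15109, Shal, CG5435, CG13361, Pdh and Cyp4p2 followed, down to 3.74. The largest falls were those of jhamt, a juvenile hormone methyltransferase, at -3.90 (SE 0.07), CG15209 at -3.86 (SE 0.11) and CG6733 at -3.82 (SE 0.13). CG13743, CG8157, CG2861, Hml, CG34045, Nepl15, CG9592, CG34377 and CG1092 followed, to -2.97. In 7 of the 12 higher and 8 of the 12 lower genes, 1 group averaged below a log2 value of 2, so their sizes and order are uncertain.

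The count was 16 without replicate A of Msh, 28 without B and 50 without C, and 602, 237 and 257 without replicates A, B and C of wild type set 2. It was 0 with the replicate letter as a block, though here too the letters showed no pairing. Against wild type set 1 after quantile normalization Mlc2, TpnC73F, Pfk, fne, PPO1, CG13743, CG2861 and CG34045 had a positive change in Msh, 0.78 for Mlc2 and 0.87 for CG13743. Those falls were thus seen only against wild type set 2. This comparison too crosses the scaled parts, so an offset between them could turn a sign and the direction is not decided. Other genes may turn as well, since only the fold nearer 0 of the 2 sets was kept. Against set 1 as deposited the contractile list turned up (adjusted p = 0.0332), and with both sets as planned its adjusted p was 1 and 5 of the 13 lists passed.

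**Figure D2:**
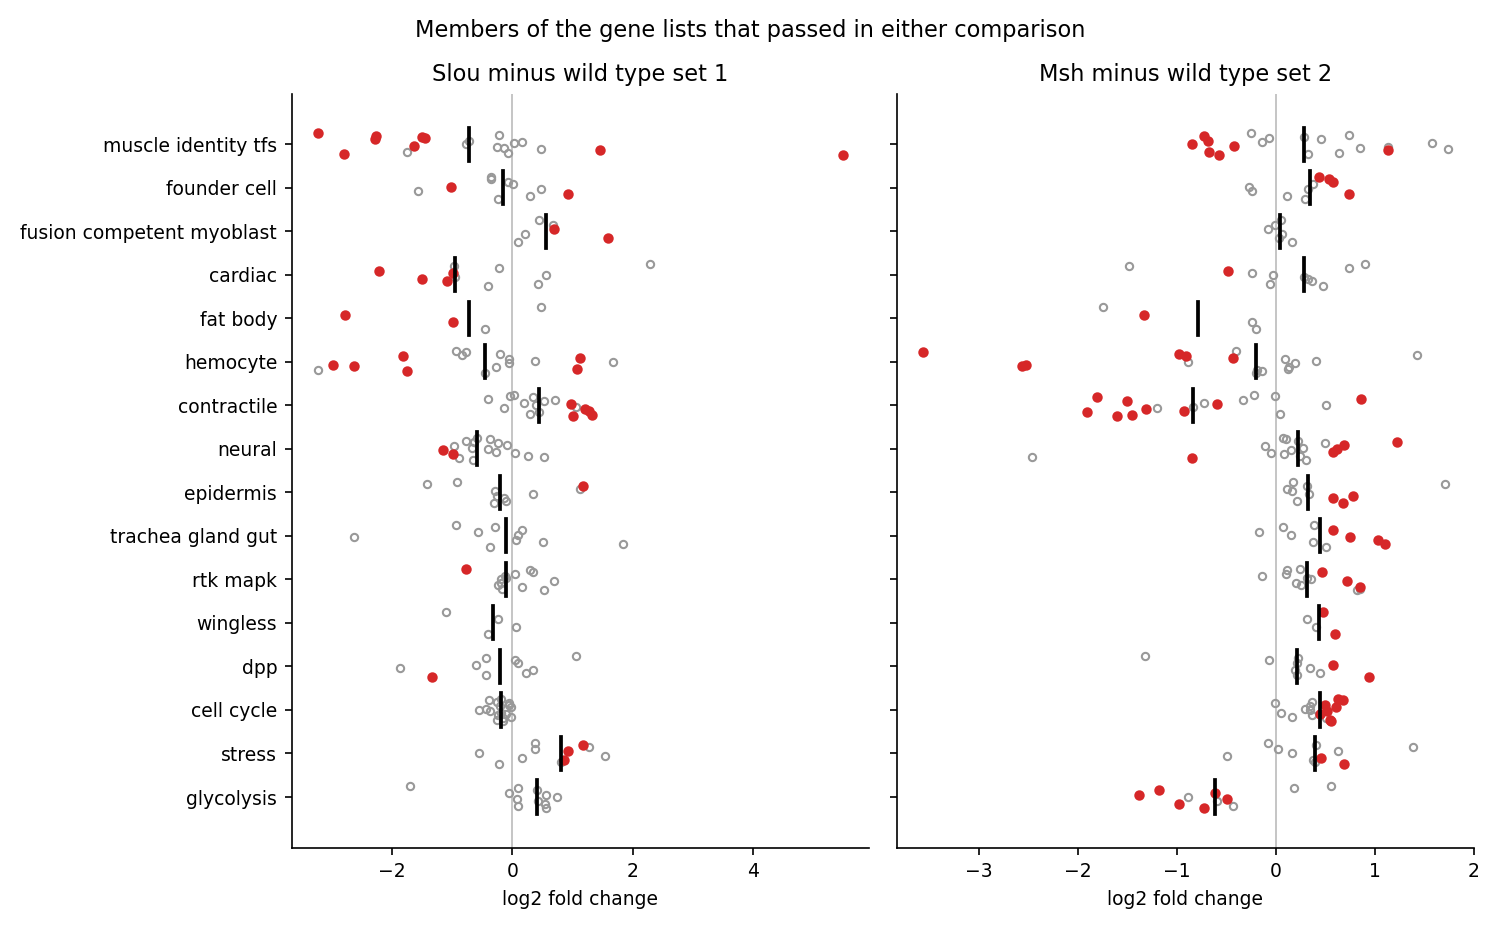
Log2 fold change of each measured member of the lists that passed in either comparison, for Slou minus wild type set 1 on the left and Msh minus wild type set 2 on the right, with separate horizontal scales. Filled red points passed, open grey points did not, and black bars are list medians, such as 0.45 for contractile genes in Slou and -0.83 in Msh. Against the other wild-type set after quantile normalization Mlc2 and TpnC73F changed sign in both, in comparisons that cross the separately scaled parts.

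The difference between the Slou effect and the Msh effect was tested directly. Contractile genes had a median difference of 1.58 (adjusted p = 7.08e-09; adjusted p = 0.00201 with an estimated correlation) and 9 of 17 members passed. Mlc2 differed by 2.78, Mlc1 by 2.62 and TpnC73F by 2.52, each up in Slou and down in Msh. Cell cycle genes had a median difference of -0.62 (adjusted p = 2.31e-11; adjusted p = 0.00149 with an estimated correlation), and glycolysis genes one of 1.04 (adjusted p = 1.53e-05; adjusted p = 0.0172 with an estimated correlation). dpp differed by -2.28, SPARC by 1.55 and slou by 6.06 (SE 0.14, adjusted p = 2.04e-07).

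In this test 1730 probe sets passed, 893 higher and 837 lower in the Slou effect, and 1059, 1036 and 1086 passed without Msh replicate A, B and C. Nach at 7.18, slou, Drl-2, Fie, Gagr, CG13743, CG34045 and Semp1 at 4.99 were the highest, and Aptx at -5.93, CG12594, MtnD, Muc68E, CG10793, Tim17b1, CG10822 and CG33159 at -4.34 the lowest. In 15 of these 16 genes, all but slou, at least 2 of the 4 groups averaged below a log2 value of 2, near background, so their sizes and order are uncertain. After quantile normalization, wild type set 2 minus set 1 had a median of 0.83 for contractile, -0.31 for cell cycle and 0.37 for glycolysis genes, and Slou minus Msh one of 0.64, -0.31 and 0.33. The planned test, which needed 3 contrasts to pass, called 499 probe sets.

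The wild-type sets differ in the scaling of the deposited values. Wild type set 2 was higher than set 1 for 9798 probe sets and lower for 75, with a median difference of 1.56 over all probe sets. After quantile normalization 3234 probe sets passed, of which 48.3% were higher, and the median difference was -0.02.

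Some genes also changed alike in the Slou and Msh arrays. Between the lists of called probe sets 40 were higher in both, where independent lists would share 6.62 (Fisher's exact test, one-sided, p = 3.68e-20). Lower in both were 56, against 7.99 (Fisher's exact test, one-sided, p = 6.19e-32). Another 30 were higher in Slou and lower in Msh, against 9.17 (exact p = 1.16e-08), and 8 lower in Slou and higher in Msh, against 5.77 (exact p = 0.222). Col4a1 and vkg, apolpp, and CG15209 fell in both, and CG13794, CG32572, klar and kek1 rose in both. Probe sets are not independent replicates, so these p-values describe overlap across probe sets only.

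Across 11982 genes the Slou and Msh fold changes had a Pearson r of 0.072 and a Spearman rho of 0.034, with no wild-type array in common; genes are not independent replicates. Set against the opposite wild-type sets after quantile normalization, r was -0.328, but there the difference between the separately scaled parts enters with opposite signs, which gives a negative r with no effect of either factor.

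**Figure D3:**
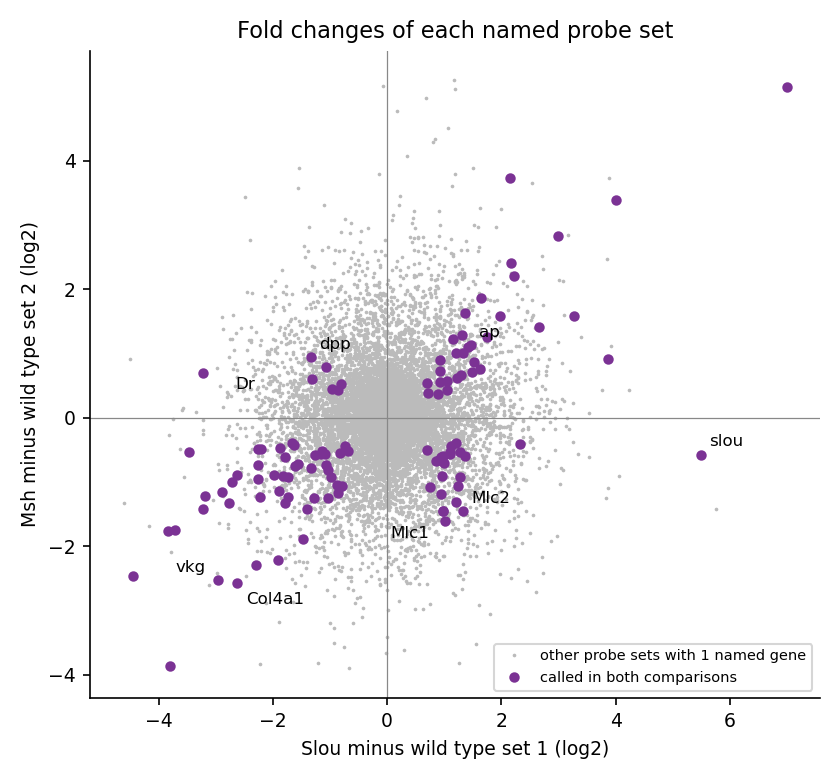
Log2 fold change of each probe set with 1 named gene in Slou minus wild type set 1 (horizontal) and Msh minus wild type set 2 (vertical). Purple points passed in both comparisons, such as Col4a1 at -2.62 and -2.57, and Mlc2 at 1.33 and -1.46. After quantile normalization Mlc2 has the opposite sign in each comparison against the other wild-type set, which crosses the separately scaled parts.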

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

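The test of a difference between the wild-type sets, and those of hemocyte and fat body genes, were chosen only after the result was seen. With 3 arrays per group, no single array was tested as standing apart.

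Effects that differed between Slou and Msh by the test of the difference and passed in opposite directions are given here, beside lists whose difference passed with an estimated correlation. Of 162 named genes and list examples, most of them picked as strongly changed, 112 differed by that test and 11 passed in opposite directions; over all probe sets 1730 of 18769 differed. The Slou effect minus the Msh effect was 2.78 for Mlc2, 2.62 for Mlc1, 2.52 for TpnC73F, 2.21 for up and 1.58 for bt, all of contractile proteins. It was 1.55 for SPARC, 1.69 for Kaz-m1, -1.29 for Brd, -2.28 for dpp, -3.93 for CG43336 and 6.06 for slou.

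The median difference between the effects was 1.58 for contractile, 1.04 for glycolysis and -0.62 for cell cycle genes. Scaling stays open: the contractile median in Msh after quantile normalization was -0.67 (95% bootstrap interval over genes -1.47 to -0.22), but the 6 arrays already shared a distribution (75th percentiles 7.56 to 7.58), so the normalization could hardly move it. A difference between the wild-type sets stays open: after quantile normalization their contractile median differed by 0.828 (0.121 to 1.44), a value that also holds any offset between the scaled parts, beside 1.57 between the effects. For embryo age, 15 genes of the ecdysone cascade had a median of -0.0278 (-0.979 to 0.156) in Msh and -0.0185 (-0.293 to 0.449) in Slou. The prediction written before the test counted medians this small as against age, with no condition on the intervals. A condition on the intervals was applied here, and they are too wide to decide, so embryo age stays open too. The overexpressed factor, the biological difference in the design, could act as well and cannot be told apart from these here. Control probe sets differed too. The Act5C 3' minus 5' difference was 2.23 in Msh and 1.44 in wild type set 2, against 1.47 in Slou and 1.44 in wild type set 1. Whether that difference bears on the pattern was not tested.

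Col4a1 and vkg, which hemocytes and fat body express, fell by over 2 on the log2 scale in both backgrounds. Fewer hemocytes in the sort are unlikely to be the whole cause, since the other 15 hemocyte genes had medians of -0.192 (-0.884 to 0.126) in Msh and -0.271 (-0.836 to 0.370) in Slou. Ppn, the most abundant of them, averaged 12.91 in wild type set 2 and 13.05 in Msh, and 11.88 in wild type set 1 and 11.61 in Slou. Others fell, with log2 changes of -3.57 for Hml, -0.97 for PPO1 and -0.91 for Glt in Msh and -1.75 for gcm and -1.82 for Glt in Slou. In Slou 2 hemocyte genes rose, among them SPARC by 1.12, while in Msh 0 rose and SPARC changed by -0.43. The hemocyte and fat body lists both hold srp. Fewer fat body cells stay open, as the 4 fat body genes had medians of -0.782 (-1.75 to -0.205) and -0.713 (-2.77 to 0.485). A sort for GFP in Twist-expressing cells need not remove either cell type, and an effect of the factors was not tested.

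Probe sets that passed the same way in both backgrounds numbered more than independent lists would give. A single chromosomal region carried over between fly lines is unlikely to account for them, since the fullest window held 9.09% (7 of 77 genes), and 17 of 100 random sets had a window as full. Noise of probe sets dim on all arrays is unlikely alone as well: above the 40th percentile, 95 were shared against 19.3 expected. The ratio was 4.93 (95% Poisson interval 3.99 to 6.02, which takes probe sets as independent). The percentile was of the mean over all arrays. Probe sets with a single group near background could stay in, and for them this test does not decide. Independent lists, however, take every probe set as equally easy to call. Over all probe sets, 30 were also higher in Slou and lower in Msh, against 9.17, and 8 the reverse, against 5.77. How much of the sharing comes from probe sets easy to call in both was not tested. A shared effect of the factors, and a difference in genetic background spread over several regions, were not tested.

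For Slou, Msh and the wild-type sets the 10 splits of 6 arrays are too few for a share under 0.05. The real split was the 1 split with the most calls in each: 434 for Slou with 1 in the highest other, 1278 for Msh with 0, and 9770 for the wild-type sets fitted alone with 0. For gene lists it was 10 for Slou with 1 in the highest other, and 13 for Msh with 0. For Slou against Msh, 2 of 100 regroupings gave at least as many calls as the real 1730, and 1 of them was the labelled grouping itself. The other, with 1828, exchanged the Msh and wild type set 2 labels, which turns the difference of the effects into their sum. The next gave 212. These counts show that the labelled groups of arrays differ, but cannot show that the Slou and Msh effects differ from each other. Since arrays of a group may be technical repeats, chance between embryo collections is not excluded.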

How the results depend on the processing

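The tests of both wild-type sets after quantile normalization were chosen only after the result was seen, as was the choice of fit. For a change listed below the cause was not tested, except that fewer probe sets were tested without dim ones and fewer arrays fitted when one was left out. The block left fewer degrees of freedom, and arrays of the same letter showed no pairing. Spread between arrays was largest near background; leaving out dim probe sets raised the counts for Slou, Msh and Slou against Msh, but not those for the wild-type sets (9243) or the lists (10 for Slou, 12 for Msh).

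For Slou, 434 calls became 387 after quantile normalization, 347 with centred arrays, 434 with a minimum fold, 572 (23 higher, 549 lower) with both sets as planned and 318 with 9 arrays. They became 1171 without dim probe sets, 2380 with an intensity trend, 1591 against set 1 in 12 arrays, 9873 against set 2, 84 against all 6 wild-type arrays and 735 against both sets after quantile normalization. With the replicate letter as a block, limma called 0 (2105 at an unadjusted p under 0.05). Leaving out 1 array gave 0 to 49: 42, 49 and 0 without wild type set 1 A, B and C (for C, 2436 at an unadjusted p under 0.05 by limma), and 41, 27 and 45 without Slou A, B and C.

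For Msh, 1278 calls became 1352 after quantile normalization, 1096 with centred arrays, 867 with a minimum fold and 1741 against set 2 in 12 arrays. They became 2971 without dim probe sets, 3621 with a trend, 9983 against set 1, 26 against all 6 wild-type arrays, 421 (415 higher, 6 lower) with both sets as planned, 231 with 9 arrays and 804 with both sets after quantile normalization. With the block, limma called 0 (3479 at an unadjusted p under 0.05). Leaving out 1 array gave 16 to 602: 602, 237 and 257 without wild type set 2 A, B and C, and 16, 28 and 50 without Msh A, B and C.

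For Slou against Msh, 1730 became 2700 without dim probe sets, 1107 with the block, 2944 with a trend, 9909 for Slou minus Msh, 11157 with the wild-type sets exchanged and 499 with all 3 contrasts as planned. Leaving out 1 array gave 1036 to 1412, with 1059, 1036 and 1086 without Msh A, B and C. Between the wild-type sets 9873 became 3234 after quantile normalization and 6631 with centred arrays, with a range of 9394 to 10004 when 1 array was left out. Of the gene lists, 10 for Slou became 0 with an estimated correlation (8 at an unadjusted p under 0.05 by limma) and 2 with both sets as planned, with 8 to 10 when 1 array was left out. For Msh, 13 became 0 with an estimated correlation (7 at an unadjusted p under 0.05 by limma) and 5 with both sets as planned, with 12 to 14 when 1 array was left out. For contractile genes the estimated correlation lay under the preset one in both comparisons, so it cannot account for their larger p. The correlation across genes of 0.072 became 0.111 without dim probe sets. After quantile normalization it was 0.109 against all 6 wild-type arrays, where shared controls alone gave 0.332 in simulations with no effect. Those simulations held no difference between the scaled parts, which in the data enters with opposite signs and lowers the correlation, so the 2 values cannot be compared. With the sets exchanged the correlation was -0.328, where that difference gives a negative value with no effect. Leaving out 1 array gave 0.0537 to 0.0766.

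In Slou these log2 changes turned negative against set 2 alone, which lies on the higher scale: CG32485 -0.38, sns -2.52, blow -1.22, Vrp1 -1.90, sing -1.15, Lsp2 -1.28, SPARC -0.86, Mlc1 -2.01, Mlc2 -2.84, up -0.71, TpnC73F -2.25, Hsp27 -2.57, kay -1.33, puc -1.66, Pfk -2.40, Ald1 -2.77, Eno -2.55, Kaz-m1 -0.20, E(spl)mdelta-HLH -0.67, ap -0.16, Pxn -0.45, rols -0.67 and bt -2.38. With both sets as planned, and with 9 arrays, CG32485, SPARC, up, Kaz-m1, E(spl)mdelta-HLH, ap, Pxn and rols had these same values. Against all 6 wild-type arrays they were sns -0.46, blow -0.26, Vrp1 -0.61, sing -0.35, Lsp2 -0.40, Mlc1 -0.50, Mlc2 -0.75, TpnC73F -0.52, Hsp27 -0.86, kay -0.21, puc -0.24, Pfk -0.92, Ald1 -1.11, Eno -0.996 and bt -0.70. With both sets after quantile normalization those that turned negative were sns -0.67, Vrp1 -0.25, Lsp2 -0.15, Mlc1 -0.14, Mlc2 -0.93, TpnC73F -0.40, Hsp27 -0.71, Pfk -0.44 and bt -0.47, while srp turned positive at 0.18. In tests of both sets, here and for Msh, the value kept was the fold nearer 0 of the 2 contrasts. Genes whose opposite change against the other set was the larger in size are therefore not listed for those tests. Lsp2 ranged from -0.66 without wild type set 1 A to 1.19 without C.

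In Msh these changes turned positive against set 1 alone, on the lower scale: jhamt 0.057, CG6733 0.19, CG13743 1.48, CG2861 0.996, CG34045 0.92, slou 0.33, srp 0.97, svp 2.20, apolpp 0.62, Lsp2 0.021, Glt 1.42, PPO1 1.97, Mlc2 2.71, TpnC73F 2.15, Mlp60A 1.20, Msp300 1.52, fne 2.58, stv 4.10, Pfk 2.23, Eno 1.73, Hex-A 1.74, Tpi 1.34, kn 1.20, Six4 1.43, eve 1.89, nau 0.94, Ptx1 1.72, glob1 0.84, fabp 0.11, Idh 0.78, Hand 1.45, Kaz-m1 0.49, SPARC 1.55, Tm2 0.93, up 1.07 and bt 2.77. With both sets as planned, and with 9 arrays, jhamt, CG6733, CG13743, CG2861, CG34045, slou, apolpp, Lsp2, Mlp60A, Msp300, glob1, fabp, Idh, Kaz-m1 and Tm2 had these same values. Against all 6 wild-type arrays they were srp 0.38, svp 0.98, Glt 0.26, PPO1 0.50, Mlc2 0.62, TpnC73F 0.42, fne 0.87, stv 1.81, Pfk 0.75, Eno 0.18, Hex-A 0.57, Tpi 0.080, kn 0.18, Six4 0.37, eve 0.61, nau 0.26, Ptx1 0.50, Hand 0.49, SPARC 0.56, up 0.072 and bt 1.09. With both sets after quantile normalization those that turned positive were CG13743 0.87, CG2861 0.43, CG34045 0.34, PPO1 0.14, Mlc2 0.78, TpnC73F 0.27, fne 0.69 and Pfk 0.32. In that test l(1)sc at -0.21, Brd at -0.21 and E(spl)mdelta-HLH at -0.0024 turned negative.

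For Slou against Msh with the wild-type sets exchanged Drl-2 was -3.06, CG13743 -5.51, CG34045 -3.81 and Semp1 -1.76; for Slou minus Msh, and with all 3 contrasts, CG13743 was -0.22. Lists turned direction against set 2 for Slou, with adjusted p values of 0.0361 for fusion-competent myoblasts, 0.0248 for contractile, 0.0939 for stress and 0.0831 for glycolysis genes, among values of 0.0248 to 0.0939. For Msh against set 1 they were 0.959 for fat body, 0.0332 for contractile and 0.235 for glycolysis genes, and with both sets as planned the adjusted p was 1 for each of these 3.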

Other observations

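The genes in this part, and their grouping, were chosen only after their values were seen; glob1, fabp and Idh come from the genes called in both comparisons, and the others from lists fixed before the data were examined.

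Of 8 measured genes of the Bearded family, whose members include inhibitors of Notch signalling, 4 fell in Slou: BobA by 0.87 (SE 0.10), Brd and Ocho by 0.86 (SE 0.10 each) and Tom by 0.73 (SE 0.09). The other 4 did not pass, with 0.34 for E(spl)m2-BFM, 0.50 for E(spl)m6-BFM, 0.30 for E(spl)malpha-BFM and -0.25 for E(spl)m4-BFM, and the family was not tested as a set. E(spl)mdelta-HLH, a Notch target, rose by 0.72 (SE 0.09) and Kaz-m1 by 0.99 (SE 0.09). The 16 Notch genes as a list did not pass in Slou, with 2 rising and 4 falling, or 7 and 4 adjusted over the list alone (adjusted p = 0.832), nor in Msh, with 3 rising and 2 falling (adjusted p = 0.141). In Msh numb rose by 0.58 (SE 0.07) and Brd by 0.44 (SE 0.07), though Brd was -0.21 against wild type set 1 after quantile normalization, while Kaz-m1 fell by 0.70 (SE 0.10). In Slou bin and HLH54F, factors of the visceral mesoderm, fell by 1.64 (SE 0.11) and 1.53 (SE 0.12); the list of 7 did not pass (adjusted p = 0.135 in Slou and 0.747 in Msh). In Msh the Hox genes Dfd and Scr rose by 0.79 (SE 0.11) and 0.76 (SE 0.14), and twi, the mesodermal determinant, by 0.91 (SE 0.15).

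glob1, a globin, fell by 2.29 in Slou and by 2.29 in Msh, fabp, a fatty acid binding protein, by 1.92 and 2.21, and Idh, an isocitrate dehydrogenase, by 2.23 and 1.23. Single members moved in lists that did not pass: in Slou Ndg fell by 1.02, edl by 0.77 and beat-IIIc by 0.98, tyn rose by 1.17, and rols rose by 0.92. In Msh Hand fell by 0.48 (SE 0.08), aub rose by 0.58 and Dark by 0.42.

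The lists that passed in neither comparison had these adjusted p values, in Slou and then Msh. They were 0.531 and 0.315 for fusion machinery, 0.0726 and 0.671 for adult muscle precursors, 0.528 and 0.106 for germline, and 0.163 and 0.818 for apoptosis. For ribosomal proteins they were 0.679 and 0.0642, for matrix and integrins 0.938 and 0.754, for guidance and adhesion 0.679 and 0.407, and for Hox genes 0.938 and 0.0546. The lists that passed in Msh had in Slou 0.696 for founder cells, 0.832 for epidermis, 0.679 for trachea, gland and gut, 0.928 for receptor tyrosine kinases, 0.0890 for Wingless and 0.318 for Dpp. Those that passed in Slou had in Msh 0.580 for fusion-competent myoblasts and 0.539 for cardiac genes.

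Hybridisation control transcripts averaged 10.08 ± 0.08 in wild type set 1, 10.01 ± 0.05 in Slou, 11.22 ± 0.25 in wild type set 2 and 10.64 ± 0.13 in Msh (SD, n = 3 each). The 3' minus 5' difference of eIF-4a probe sets was 1.65 ± 0.04, 1.62 ± 0.03, 1.52 ± 0.10 and 1.74 ± 0.07 in that order.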
